A study of Homo sapiens with 28 samples.

How the data were processed

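Messenger RNA of the leukaemia lines OCI-AML2, MV4-11 and MOLM-13 was measured in 28 libraries of 14 groups, with 2 libraries in each group. Per the labels, cells carried a guide against luciferase (control) or PCGF1, or in OCI-AML2 BCOR, and were kept 6 days in DMSO or 1 µM VTP50469. Libraries were made with the NEBNext Ultra RNA kit and read as 150-base pairs on a HiSeq 4000. The protocol does not mark strands, so levels of antisense and overlapping genes are uncertain. The submitters' processing notes name STAR 2.5.1b and hg38. The gene counter, annotation release and size factor method are not given in the sources used here.

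The signal values deposited by the authors are gene read counts divided by 1 size factor per library, in 1 table per line of 61552 genes, 41057 of them with a symbol. This was checked on the values, which in each library are whole multiples of a single step (100% of them within a tolerance of 0.001). Division by the step gave the reads. In 1 VTP50469 library of MV4-11 control cells and 1 of the OCI-AML2 group labelled BCOR knockout the size factor was close to 1 (1.01 and 0.989). The values of these 2 are whole multiples too, but they were left out of edgeR, DESeq2 and the chi-square as a precaution, while their reads enter depth, thinning and simulations. The 2 tools used 11, 7 and 8 libraries of OCI-AML2, MV4-11 and MOLM-13. The tables were normalised separately, and no test was made across lines.

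Library totals spanned a factor of 2.46, and tested genes held 99.9% of the reads. Replicates had a Pearson correlation across genes of 0.981 to 0.989. Their squared differences were 1.91 to 9.49 times those of counting error alone (chi-square per degree of freedom, 12 groups), so reads alone do not set the precision.

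Genes with a value of at least 10 in at least 2 libraries of a line were tested, 14668 in OCI-AML2, 14809 in MV4-11 and 14795 in MOLM-13. Limma 3.58.1 in R 4.3.3 was fitted to log2(value + 1) over all libraries of a line with 1 mean per group, and empirical Bayes with trend and robust options. Tests were two-sided. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called. Fold changes on this scale understate changes of weakly expressed genes. For genes with 1 to 3 reads in a group the ratio of group means is given with a 95% exact interval for counting error. The 21 comparisons were inhibitor against DMSO within each kind of cell, knockout against control within each treatment, their interaction, and the libraries labelled BCOR knockout against PCGF1 knockout. Design, comparisons, 22 gene lists and the rule for naming genes were fixed before the data were examined.

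The rule names PCGF1, BCOR, MYC, MEIS1 and HOXA9 in every comparison. In each comparison it allows up to 5 called genes each way with the largest changes, at least 2-fold, with a mean of at least 100 and groups that do not overlap. It adds up to 10 genes each way called in the same direction in all 3 lines, ranked by their smallest change, and up to 4 members of a list with the smallest adjusted p and members against its direction. The text names some of the genes allowed, and genes with no reads in a group were passed over.

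The lists were menin-MLL target genes, PRC1.1 subunits, other PRC1 and PRC2 subunits, menin, MLL and fusion partner complex genes, the MYC network, ribosome biogenesis and MYC-associated genes, monocyte and macrophage markers, primary granule and granulocyte progenitor genes, neutrophil maturation genes, stem and progenitor genes, the BCL2 family, cell cycle genes, MHC class II genes, interferon response genes, p53 target genes, integrated stress response genes, cholesterol synthesis genes, HOXB, HOXC and HOXD genes, developmental transcription factors of other tissues, B cell, T and NK cell, and erythroid and megakaryocyte markers. Members came from general knowledge of these processes. Lists with at least 5 tested members, 19 in each line, were tested with camera at a preset correlation of 0.01, adjusted over lists. Camera with an estimated correlation is given as a second adjusted p where it ends a call. Medians that change when members at 0 in a group are set to a floor of 3 reads over the group are given both ways. Overlaps between lines are set against the product of the shares called. For the overlap of the 2 guides in OCI-AML2, both groups were simulated 20 times with the means of the control group they share.

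In simulated data with the group sizes of each line 200 genes were changed. Limma recovered 45 of 67 genes changed 1.5-fold in OCI-AML2, 51 in MV4-11 and 39 in MOLM-13. It recovered 59, 60 and 61 of 67 changed 2-fold and 66 of 66 changed 4-fold in each, with 14, 11 and 10 false calls. In each line camera called the changed list and 0 of 40 random ones, which do not test its preset correlation.

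The alternatives were a pseudocount of 5, no filter, a stricter filter (50 in at least 2 libraries), TMM rescaling, edgeR 4.0.16 and DESeq2 1.42.0 on the recovered reads, the replicate number as a block, and each library left out in turn. Thinning a line's libraries to the shallowest was added after seeing the data. Coordinates are from GENCODE 29. Figures were drawn with matplotlib 3.10.9.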

Results

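RNA was sequenced from 3 human acute myeloid leukaemia cell lines with a rearranged KMT2A gene, OCI-AML2, MV4-11 and MOLM-13. Cells carried a control guide against luciferase or a guide against PCGF1, and OCI-AML2 cells also a guide against BCOR. PCGF1 and BCOR are subunits of PRC1.1, a Polycomb complex that places ubiquitin on histone H2A. Each kind of cell was kept for 6 days in DMSO or in 1 µM VTP50469, a small molecule that blocks the binding of menin to KMT2A proteins. The 28 libraries formed 14 groups of 2. The labels do not state that the libraries of a group came from separate cultures. Every p-value therefore measures the spread between these samples, which may be technical. In OCI-AML2 the deepest library had 2.46 times the reads of the shallowest, against 1.40 times in MV4-11 and 1.44 times in MOLM-13. Values are normalised read counts, given as mean ± SD with n = 2 per group. Changes are log2 fold changes ± SE on the log2(value + 1) scale with limma's Benjamini-Hochberg adjusted p. Tables were scaled per line, so levels are compared and tested within a line only.

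The targeted genes were examined first, in every library. PCGF1 (ENSG00000115289, chromosome 2, 74505043 to 74508580 on the minus strand of GRCh38) was lower in each library labelled PCGF1 knockout than in each control library of the same line and treatment. In OCI-AML2 under DMSO the control libraries held 426 and 383 normalised counts and the knockout libraries 196 and 226. The values were 433 and 455 against 246 and 298 in MV4-11, and 363 and 339 against 239.9 and 169 in MOLM-13. Under DMSO PCGF1 changed by −0.94 ± 0.12, adjusted p = 8.77e-07, in OCI-AML2. The change was −0.71 ± 0.11, adjusted p = 4.31e-05, in MV4-11 and −0.80 ± 0.17, adjusted p = 0.00368, in MOLM-13. Under VTP50469 it was −0.67 ± 0.12, adjusted p = 3.82e-05, in OCI-AML2, −1.01 ± 0.11, adjusted p = 1.5e-07, in MV4-11 and −0.97 ± 0.17, adjusted p = 0.000477, in MOLM-13. An edited gene can still be transcribed, so these levels do not measure the protein. The inhibitor itself lowered PCGF1 in OCI-AML2 control cells (−0.46 ± 0.12, adjusted p = 0.00246). This call was lost without control DMSO replicate 1. The inhibitor did not change PCGF1 detectably in MV4-11 (0.25 ± 0.11, adjusted p = 0.0653) or MOLM-13 (−0.04 ± 0.17, adjusted p = 0.894) control cells.

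BCOR (ENSG00000183337, chromosome X, 40049815 to 40177329 on the minus strand) went against its label. Under DMSO the OCI-AML2 libraries labelled BCOR knockout held 4675 and 4927 normalised counts, against 2720.1 and 2649 in control cells (0.84 ± 0.05, adjusted p = 6.82e-11). Under VTP50469 they held 5185 and 5011, against 4962 and 5148 (0.01 ± 0.05, adjusted p = 0.887). A frameshift need not lower the transcript, so the level neither shows nor excludes the edit. VTP50469 raised BCOR in control cells of OCI-AML2 (0.91 ± 0.05, adjusted p = 3.22e-13) and MV4-11 (0.68 ± 0.06, adjusted p = 1.84e-08). No change was detected in MOLM-13 (−0.08 ± 0.08, adjusted p = 0.494), and the difference between lines was not tested. Under DMSO BCOR was also higher in PCGF1 knockout than in control cells of OCI-AML2 (0.55 ± 0.05, adjusted p = 3.94e-09) and MV4-11 (0.45 ± 0.06, adjusted p = 1.58e-05). In MOLM-13 it was called higher (0.32 ± 0.08, adjusted p = 0.0129). That call was lost without control DMSO replicate 1 or PCGF1 DMSO replicate 1.

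**Figure D1:**
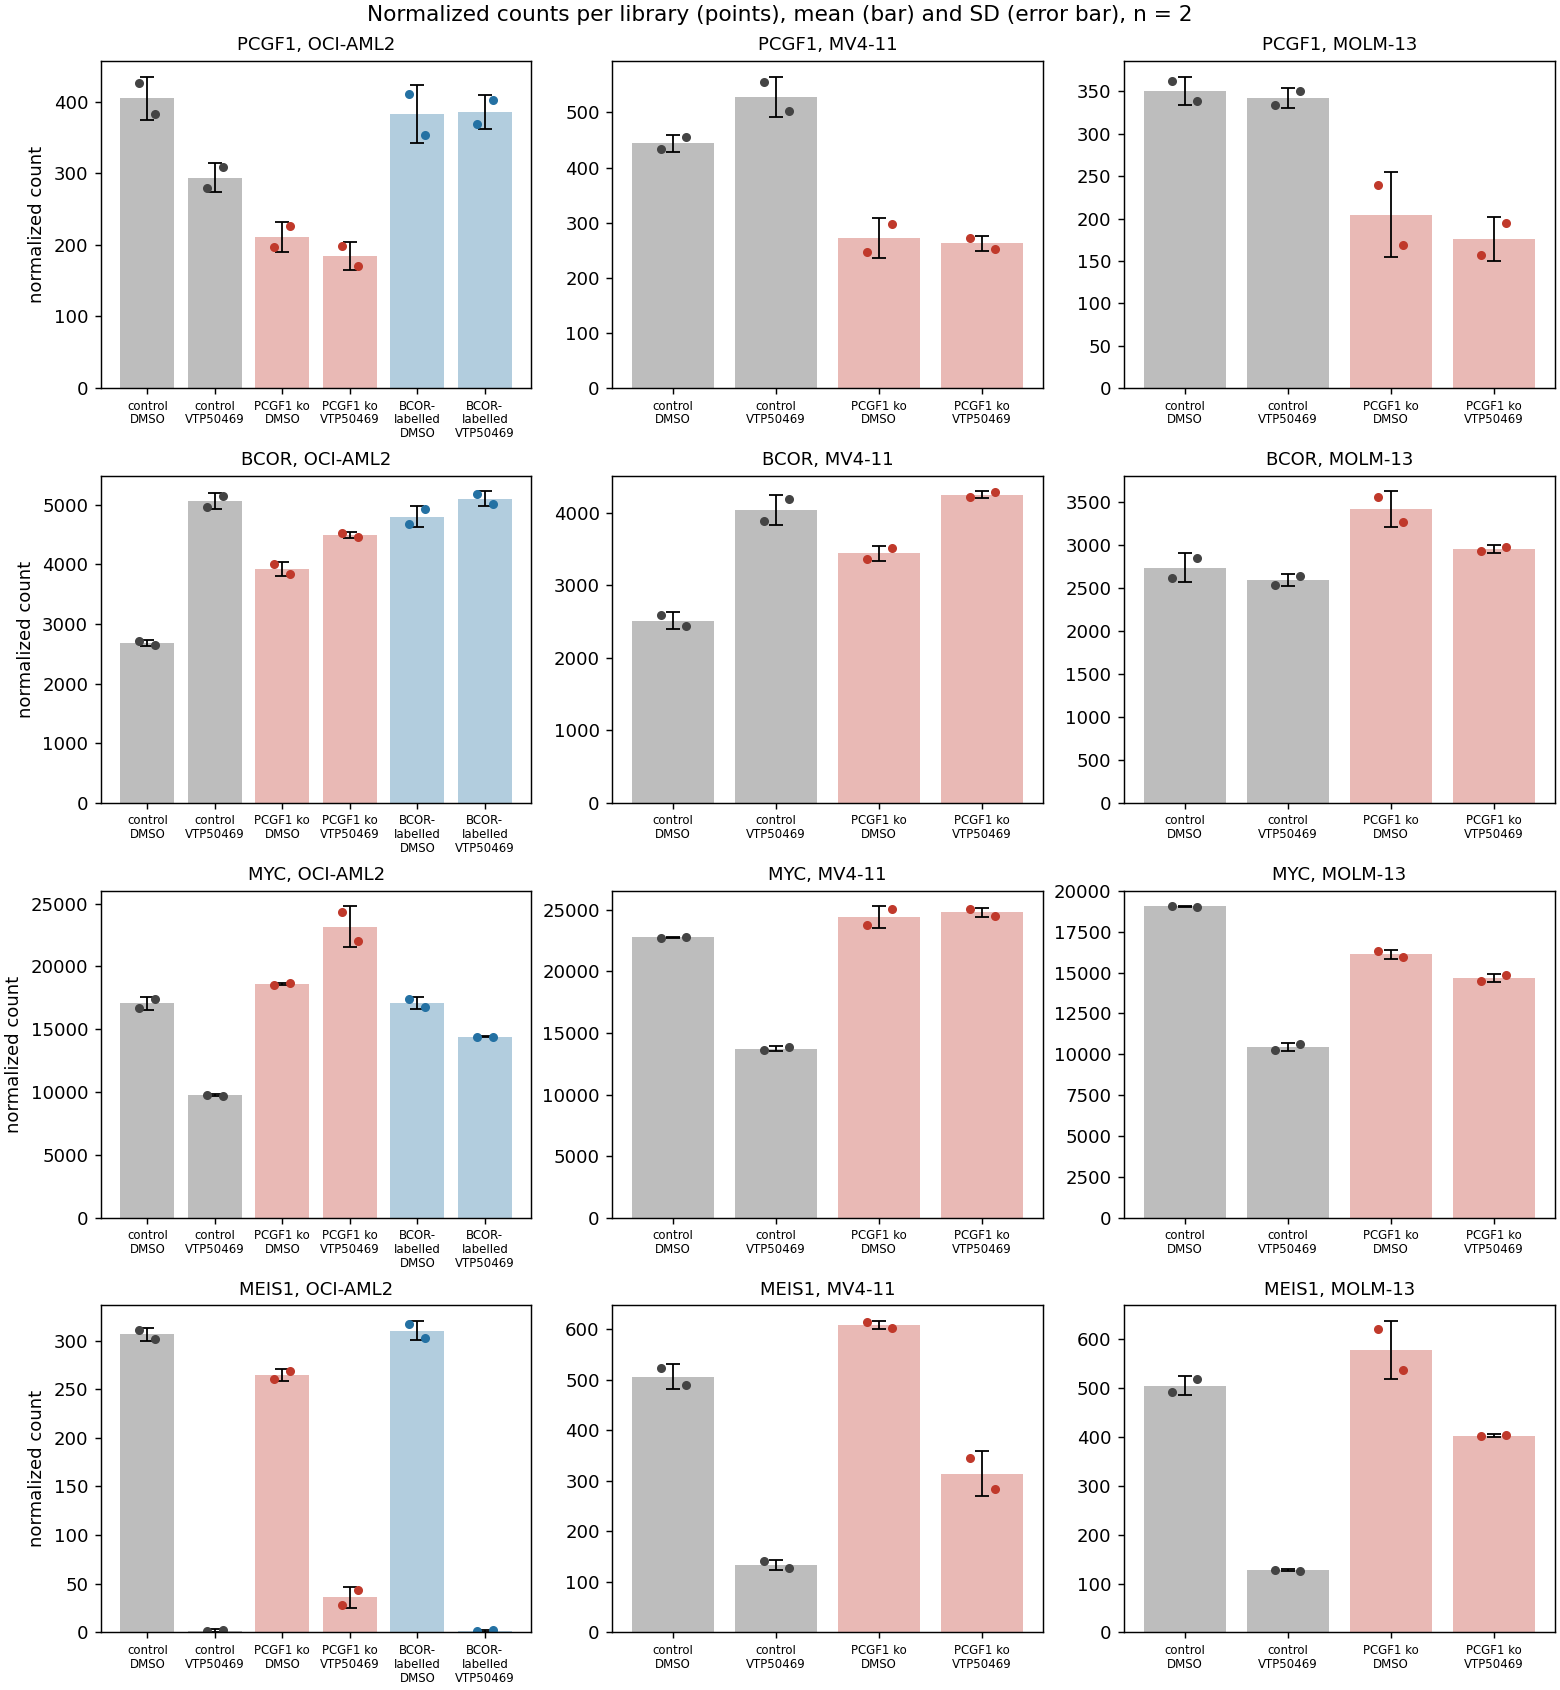
Normalised counts of PCGF1, BCOR, MYC and MEIS1 per group in each line, as bars of the mean with SD (n = 2) and a point per library, each line on its own scale. PCGF1 is lower in each PCGF1 knockout group, and under DMSO BCOR is at 4801 ± 178 in the libraries labelled BCOR knockout against 2684 ± 50.5 in control.

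The first 2 principal components of the log2 values held 42.5% and 21.8% of the variance in OCI-AML2, 56.1% and 18.8% in MV4-11, and 54.8% and 17.9% in MOLM-13.

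**Figure D2:**
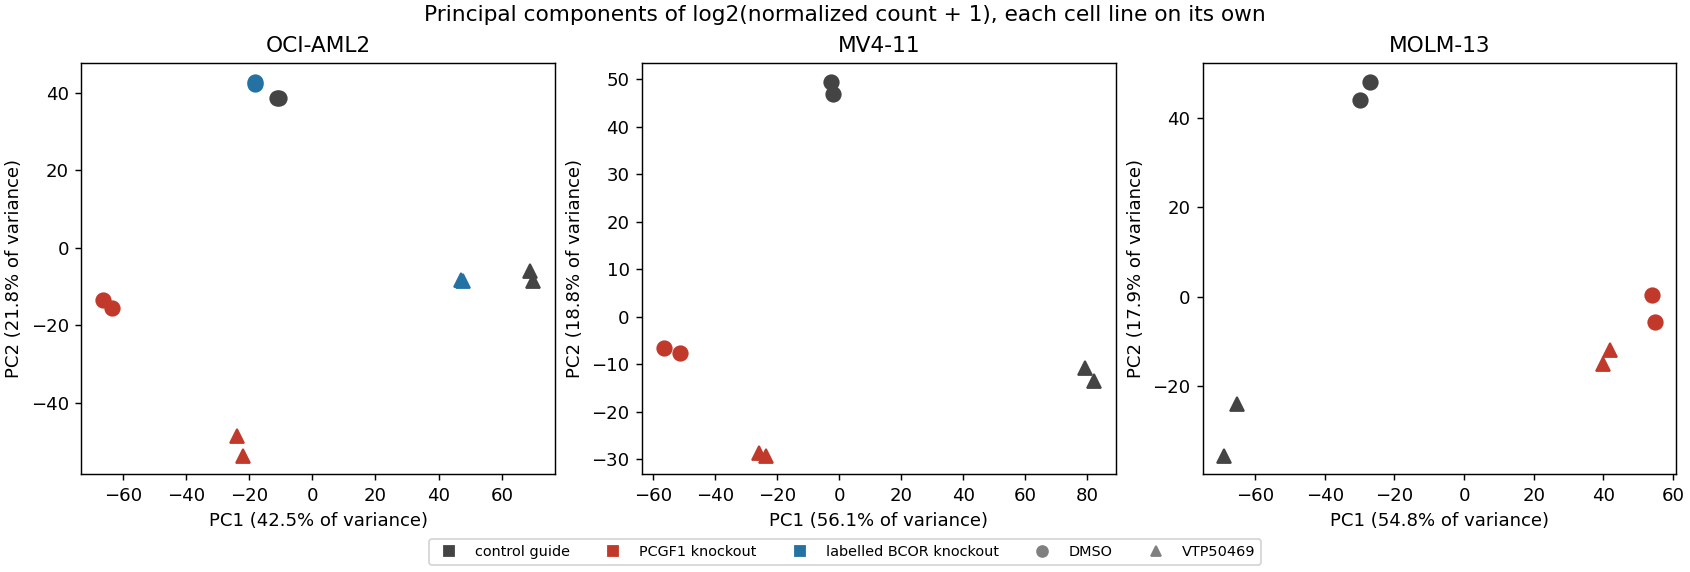
First 2 principal components in each line, with 1 point per library and the percent of variance on each axis. In OCI-AML2 the libraries labelled BCOR knockout lie beside control in DMSO (first component −18.0 and −18.2) and short of it in VTP50469 (46.9 and 47.6).

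The response of control cells to VTP50469 was compared first. In every line mitochondrial transcripts took a higher share of their reads under VTP50469 than in DMSO (1.83% and 2.08% against 1.42% and 1.27% in OCI-AML2, 2.16% and 2.67% against 1.21% and 1.37% in MV4-11, 2.47% and 2.28% against 1.46% and 1.54% in MOLM-13). MEIS1, a homeobox gene that KMT2A fusion proteins keep on in leukaemia (ENSG00000143995, chromosome 2, 66433452 to 66573869 on the plus strand), fell in all 3 lines. In OCI-AML2 its 977 reads under DMSO became 3 reads (180.2-fold, 95% exact interval 61.5 to 875 for counting error alone). In MV4-11 MEIS1 went from 507 ± 24.4 to 134 ± 9.87 (−1.91 ± 0.11, adjusted p = 9.58e-12). In MOLM-13 it went from 505 ± 19.3 to 127 ± 2.05 (−1.98 ± 0.12, adjusted p = 6.48e-08). MYC (ENSG00000136997, chromosome 8, 127735434 to 127741434 on the plus strand), which drives growth and ribosome production, also fell. Its change was −0.81 ± 0.05, adjusted p = 3.89e-12, in OCI-AML2, −0.73 ± 0.06, adjusted p = 3.09e-09, in MV4-11 and −0.87 ± 0.07, adjusted p = 1.05e-06, in MOLM-13. HOXA9 (ENSG00000078399, chromosome 7, 27162435 to 27175180 on the minus strand), a partner of MEIS1, fell in MOLM-13 (−0.74 ± 0.08, adjusted p = 1.47e-05) and rose in OCI-AML2 (0.36 ± 0.06, adjusted p = 7.44e-05). In MV4-11 its change was 0.21 ± 0.07, adjusted p = 0.0186. This call was lost with DESeq2 and without control DMSO replicate 1 or 2 or control VTP50469 replicate 2.

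Menin-MLL target genes were called lower as a list in each line, each call being lost with an estimated correlation. In MOLM-13 19 of 21 measured members fell (19 adjusted over the list alone), with a median log2 fold change −0.96, camera adjusted p = 8.09e-13, adjusted p = 0.0918 with an estimated correlation. In OCI-AML2 5 of 20 measured members rose and 12 fell (5 and 12 adjusted over the list alone), with a median log2 fold change −0.61, camera adjusted p = 2.42e-05, adjusted p = 0.106 with an estimated correlation. In MV4-11 6 of 20 measured members rose and 11 fell (6 and 12 adjusted over the list alone), with a median log2 fold change −0.56, camera adjusted p = 0.00558, adjusted p = 0.296 with an estimated correlation. MEF2C, a transcription factor of myeloid leukaemia, fell in OCI-AML2 (−2.78 ± 0.06, adjusted p = 6.49e-20), MV4-11 (−2.92 ± 0.07, adjusted p = 4.8e-18) and MOLM-13 (−1.49 ± 0.09, adjusted p = 7.63e-08). HOXA10 went against the list in OCI-AML2 (0.82 ± 0.06, adjusted p = 1.71e-10) and MV4-11 (1.26 ± 0.07, adjusted p = 9.17e-12). The developmental factor DACH1 fell in all 3 lines (−4.65, −2.86 and −1.94 in OCI-AML2, MV4-11 and MOLM-13, adjusted p at most 1.4e-08). SOCS2, a suppressor of cytokine signalling, went from 3133 reads to 2 in OCI-AML2 (867-fold, 95% exact interval 239.7 to 7159.6). In MV4-11 it fell from 1271 ± 51.2 to 207 ± 8.46 (adjusted p = 3.9e-15). GATA2, a factor of blood stem cells, fell in OCI-AML2 (−3.34 ± 0.08, adjusted p = 4.07e-20) and MV4-11 (−4.0 ± 0.21, adjusted p = 5.61e-12). The stem and progenitor list was called lower in OCI-AML2 (median log2 fold change −0.89, camera adjusted p = 0.00591, adjusted p = 0.106 with an estimated correlation) and MV4-11 (median log2 fold change −0.70, camera adjusted p = 0.0246, adjusted p = 0.136 with an estimated correlation). Both calls were lost with either other filter on low values, and the latter with DESeq2.

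Genes of mature myeloid cells rose in all 3 lines. Of the monocyte and macrophage markers in OCI-AML2, 26 of 29 measured members rose and 3 fell (26 and 3 adjusted over the list alone), with a median log2 fold change 1.56, camera adjusted p = 6.48e-15. In MV4-11 28 of 31 measured members rose and 2 fell (28 and 2 adjusted over the list alone), with a median log2 fold change 1.83, camera adjusted p = 1.15e-14, adjusted p = 0.0587 with an estimated correlation. In MOLM-13 22 of 28 measured members rose and 2 fell (23 and 2 adjusted over the list alone), with a median log2 fold change 1.48, camera adjusted p = 1.5e-12. LYZ, the lysozyme of myeloid cells, rose in OCI-AML2 (5.26 ± 0.06, adjusted p = 3.13e-24) and MOLM-13 (3.04 ± 0.09, adjusted p = 4.62e-11). CCR2, a chemokine receptor of monocytes, rose in MV4-11 (3.38 ± 0.08, adjusted p = 8.99e-18). CD4 fell in OCI-AML2 (−0.74 ± 0.08, adjusted p = 3.93e-08) and MV4-11 (−0.27 ± 0.06, adjusted p = 0.0016), and the monocyte factor IRF8 fell in MOLM-13 (−0.60 ± 0.07, adjusted p = 2.98e-05). Primary granule and granulocyte progenitor genes rose in OCI-AML2 (median log2 fold change 0.96, camera adjusted p = 2.64e-06, adjusted p = 0.144 with an estimated correlation), MV4-11 (median log2 fold change 2.70, camera adjusted p = 1.12e-12, adjusted p = 0.0587 with an estimated correlation) and MOLM-13 (median log2 fold change 0.77, camera adjusted p = 1.14e-06, adjusted p = 0.18 with an estimated correlation). ELANE, neutrophil elastase, rose in MV4-11 (3.48 ± 0.07, adjusted p = 6.47e-19) and MPO, myeloperoxidase, in MOLM-13 (3.62 ± 0.11, adjusted p = 1.3e-10). Neutrophil maturation genes rose in OCI-AML2 (median log2 fold change 2.72, camera adjusted p = 2.09e-05, adjusted p = 0.106 with an estimated correlation), MV4-11 (median log2 fold change 2.22, camera adjusted p = 0.00011, adjusted p = 0.0587 with an estimated correlation) and MOLM-13 (median log2 fold change 2.52, camera adjusted p = 1.86e-05, adjusted p = 0.18 with an estimated correlation, median 1.49 without a filter). The scavenger receptor CD36 rose by 5.39, 4.36 and 4.47 in OCI-AML2, MV4-11 and MOLM-13 (adjusted p at most 2.15e-05). The protease inhibitor SLPI rose by 7.19, 9.05 and 4.31 (adjusted p at most 2.95e-06) and annexin ANXA1 by 4.13, 5.09 and 3.55 (adjusted p at most 2.07e-09).

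Ribosome biogenesis and MYC-associated genes fell in control cells given VTP50469. In MOLM-13 49 of 50 measured members fell (49 adjusted over the list alone), with a median log2 fold change −0.63, camera adjusted p = 2.54e-24. In OCI-AML2 45 of 50 measured members fell (45 and 1 adjusted over the list alone), with a median log2 fold change −0.55, camera adjusted p = 9.99e-19. In MV4-11 3 of 50 measured members rose and 33 fell (4 and 34 adjusted over the list alone), with a median log2 fold change −0.28, camera adjusted p = 3.34e-07, adjusted p = 0.128 with an estimated correlation. BOP1, a factor of ribosome assembly, fell in OCI-AML2 (−1.02 ± 0.05, adjusted p = 1.29e-13) and MV4-11 (−1.03 ± 0.07, adjusted p = 1.95e-10), while PLK4 rose in MV4-11 (0.60 ± 0.09, adjusted p = 7.53e-06). MHC class II genes, which present antigen, rose in OCI-AML2 (median log2 fold change 1.85, camera adjusted p = 0.000542, adjusted p = 0.106 with an estimated correlation), MV4-11 (median log2 fold change 2.64, camera adjusted p = 4.85e-10, adjusted p = 0.0587 with an estimated correlation) and MOLM-13 (median log2 fold change 0.82, camera adjusted p = 0.00733, adjusted p = 0.18 with an estimated correlation, median 0.51 without a filter). Cholesterol synthesis genes rose in 2 lines and fell in MOLM-13. In OCI-AML2 19 of 20 measured members rose (19 adjusted over the list alone), with a median log2 fold change 0.68, camera adjusted p = 5.2e-10, adjusted p = 0.106 with an estimated correlation. In MV4-11 17 of 20 measured members rose and 1 fell (17 and 1 adjusted over the list alone), with a median log2 fold change 0.66, camera adjusted p = 4.11e-08, adjusted p = 0.107 with an estimated correlation. In MOLM-13 14 of 20 measured members fell (16 adjusted over the list alone), with a median log2 fold change −0.49, camera adjusted p = 7.42e-07, adjusted p = 0.248 with an estimated correlation. Squalene epoxidase SQLE rose in MV4-11 (1.05 ± 0.08, adjusted p = 3e-10) and fell in MOLM-13 (−0.93 ± 0.09, adjusted p = 6.15e-06). Integrated stress response genes fell in MV4-11 (median log2 fold change −0.97, camera adjusted p = 5.57e-12, adjusted p = 0.0658 with an estimated correlation), with DDIT4 down (−2.51 ± 0.07, adjusted p = 6.8e-17). Interferon response genes rose in MV4-11 (median log2 fold change 0.72, camera adjusted p = 5.43e-06, adjusted p = 0.0587 with an estimated correlation). Menin, MLL and fusion partner complex genes fell in MV4-11 (median log2 fold change −0.27, camera adjusted p = 0.00655, adjusted p = 0.296 with an estimated correlation, median −0.15 with edgeR and −0.15 with DESeq2), among them the methyltransferase DOT1L (−1.09 ± 0.08, adjusted p = 6.34e-09). The median was −0.16 without control DMSO replicate 1 and −0.15 without control VTP50469 replicate 1. Cell cycle genes fell in MOLM-13 (median log2 fold change −0.46, camera adjusted p = 2.2e-06, adjusted p = 0.281 with an estimated correlation), with the replication licensing gene MCM2 down (−1.16 ± 0.09, adjusted p = 5.36e-07).

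**Figure D3:**
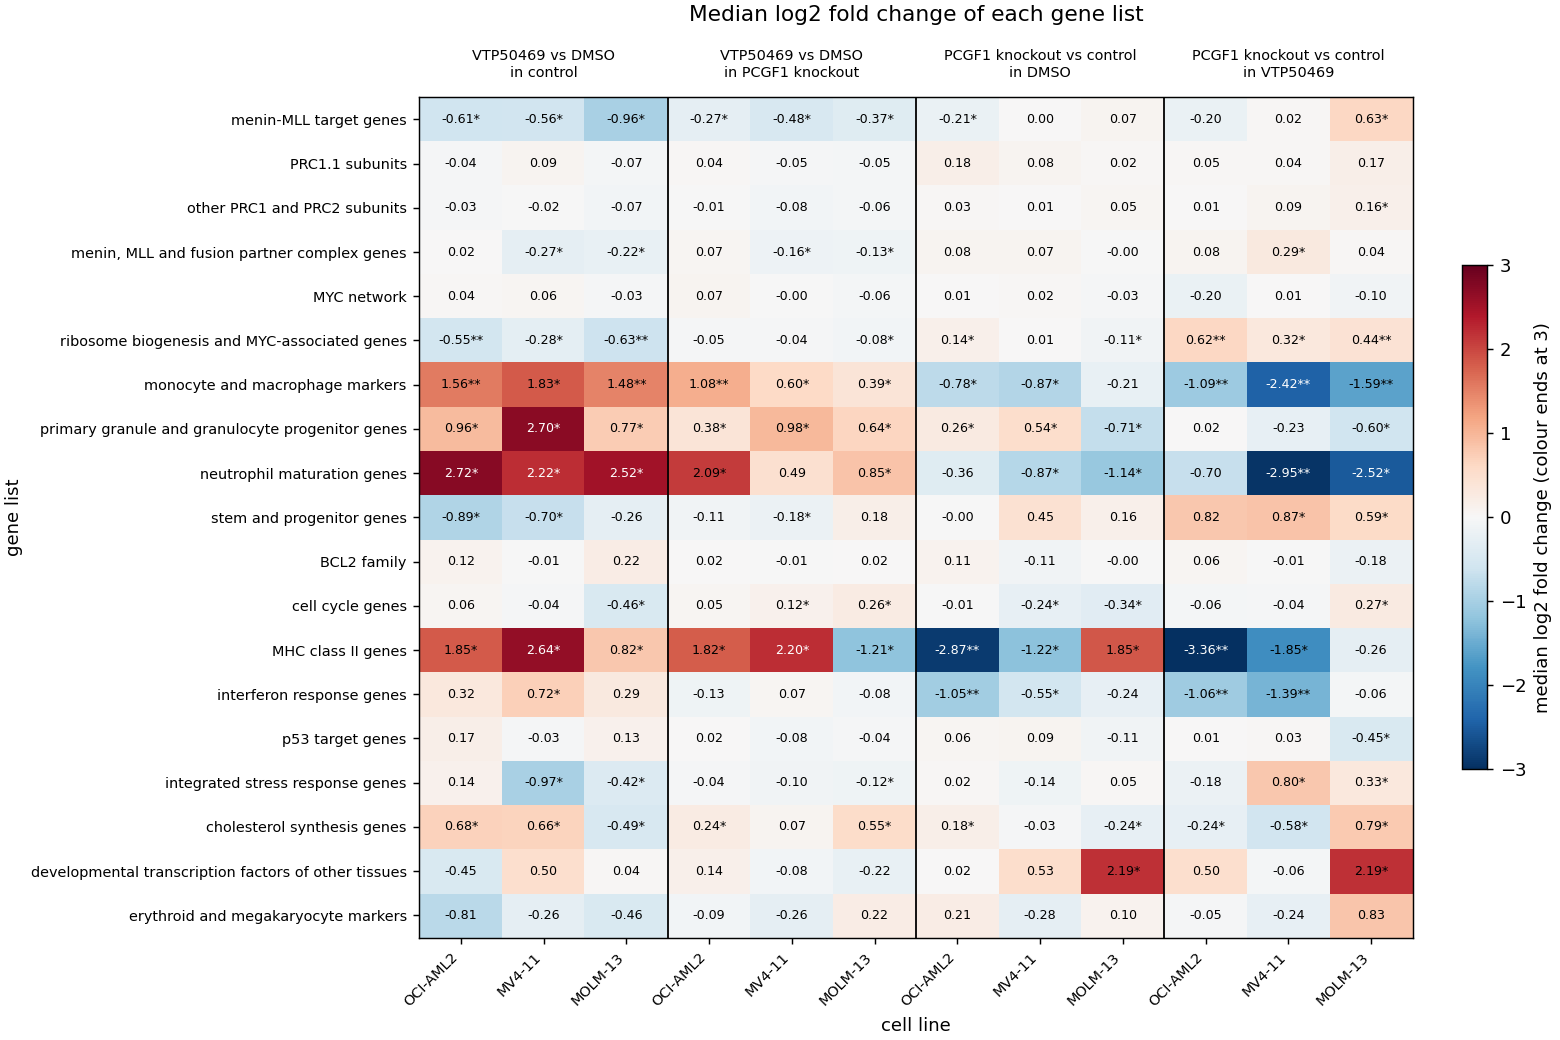
Median log2 fold change of 19 gene lists (vertical axis) in 4 comparisons for each line (horizontal axis), with colours ending at 3 and stars for a camera adjusted p under 0.05. Monocyte and macrophage markers are red in control cells given VTP50469 (1.56, 1.83 and 1.48 in OCI-AML2, MV4-11 and MOLM-13) and blue in PCGF1 knockout against control cells under VTP50469 (−1.09, −2.42 and −1.59).

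Over all tested genes, limma called 6771 of 14668 in OCI-AML2 between treatments of control cells, 3390 higher and 3381 lower. It called 7241 of 14809 in MV4-11 (3549 and 3692) and 5167 of 14795 in MOLM-13 (2383 and 2784). Of 13302 genes tested in every line, 813 were called higher and 951 lower in all 3, against 129.9 and 159 for independent lists of those sizes. Of 5741 genes called in at least 2 lines, 1228 were called in opposite directions. Without MOLM-13 control VTP50469 replicate 1 that line's count was 3252 (1368 higher), and with DESeq2 the MV4-11 count was 4139.

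PCGF1 knockout was then compared with control in DMSO. Every line had the same PCGF1 guide per the labels, so its effects beyond PCGF1 cannot be told apart from PCGF1 loss. Mitochondrial shares in the knockout, 1.48% and 1.48% in OCI-AML2, 1.68% and 1.97% in MV4-11 and 2.04% and 1.66% in MOLM-13, were above those of control. MEIS1 was not called in OCI-AML2 (−0.21 ± 0.31, adjusted p = 0.635), MV4-11 (0.27 ± 0.11, adjusted p = 0.089) or MOLM-13 (0.19 ± 0.12, adjusted p = 0.272). MYC was not called in OCI-AML2 (0.12 ± 0.05, adjusted p = 0.0558) or MV4-11 (0.10 ± 0.06, adjusted p = 0.255). In MOLM-13 MYC was called lower (−0.24 ± 0.07, adjusted p = 0.0274), and the call was lost without any single library of the control DMSO, control VTP50469 or PCGF1 DMSO groups. HOXA9 was not called in any line (−0.11, −0.14 and −0.09 in OCI-AML2, MV4-11 and MOLM-13, adjusted p of 0.18, 0.149 and 0.479). PTPRU, a receptor tyrosine phosphatase, rose in each line. It went from 307 ± 10 to 1660.3 ± 43.5 in OCI-AML2 (2.43 ± 0.11, adjusted p = 5.28e-14) and from 72.5 ± 4.4 to 1394 ± 113 in MV4-11 (4.24 ± 0.14, adjusted p = 4.39e-15). In MOLM-13 it went from 5.88 ± 5.34 to 362 ± 27.4 (5.98 ± 0.50, adjusted p = 2.63e-06). The membrane metalloprotease MMP15 rose by 3.62, 3.12 and 2.76 in OCI-AML2, MV4-11 and MOLM-13 (adjusted p at most 1.05e-06) and the Notch effector HES7 by 2.81, 2.27 and 3.21 (adjusted p at most 8.61e-05). The sorting receptor SORL1 fell from 426 ± 5.71 to 52.1 ± 5.37 in OCI-AML2 (−3.01 ± 0.09, adjusted p = 5.55e-17). It fell from 394 ± 78.3 to 42.4 ± 0.32 in MV4-11 (−3.17 ± 0.12, adjusted p = 5.37e-14) and from 785 ± 32.3 to 219.5 ± 3.03 in MOLM-13 (−1.83 ± 0.10, adjusted p = 2.62e-08).

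Some of the gene lists called with PCGF1 loss in DMSO are given by line, and differences between lines were not tested. Monocyte and macrophage markers fell in MV4-11, where 1 of 31 measured members rose and 23 fell (1 and 24 adjusted over the list alone), with a median log2 fold change −0.87, camera adjusted p = 7.1e-18, adjusted p = 0.0601 with an estimated correlation, median −1.56 with edgeR and −1.57 with DESeq2. There CCR2 went from 1195 ± 48.9 to 35 ± 2.56 (−5.06 ± 0.08, adjusted p = 1.7e-20). In OCI-AML2 7 of 29 measured members rose and 20 fell (7 and 21 adjusted over the list alone), with a median log2 fold change −0.78, camera adjusted p = 1.9e-05, adjusted p = 0.0724 with an estimated correlation. CSF1R, the macrophage growth factor receptor, fell there (−3.99 ± 0.11, adjusted p = 1.05e-17), while FCN1 (3.27 ± 0.28, adjusted p = 4.28e-09) and CD68 (0.51 ± 0.06, adjusted p = 1.06e-07) rose. In MOLM-13 the list was not called (median log2 fold change −0.21, camera adjusted p = 0.168), with MNDA lower (−3.68 ± 0.29, adjusted p = 7.84e-07). Primary granule genes rose in MV4-11 (median log2 fold change 0.54, camera adjusted p = 0.000169, adjusted p = 0.215 with an estimated correlation). They were called higher in OCI-AML2 (median log2 fold change 0.26, camera adjusted p = 0.0362, adjusted p = 0.708 with an estimated correlation, median 0.46 with the stricter filter), a call lost without BCOR DMSO replicate 1 or 2. They were called lower in MOLM-13 (median log2 fold change −0.71, camera adjusted p = 0.0292, adjusted p = 0.448 with an estimated correlation, median −0.38 with a pseudocount of 5), a call lost without control DMSO replicate 1 or PCGF1 DMSO replicate 2. ELANE rose from 388 ± 22.9 to 6032 ± 194 in MV4-11 (3.96 ± 0.07, adjusted p = 2.66e-20). MPO fell in MOLM-13 (−2.55 ± 0.11, adjusted p = 6.49e-09). MHC class II genes fell in OCI-AML2, where 11 of 11 measured members fell (11 adjusted over the list alone), with a median log2 fold change −2.87, camera adjusted p = 3.74e-09, median −1.79 with a pseudocount of 5. In MV4-11 1 of 11 measured members rose and 7 fell (1 and 7 adjusted over the list alone), with a median log2 fold change −1.22, camera adjusted p = 0.000169, adjusted p = 0.189 with an estimated correlation, CIITA, the activator of the class, being the member called higher (0.31 ± 0.09, adjusted p = 0.0199), a call lost with DESeq2 and without any library of either group. In MOLM-13 5 of 8 measured members rose (5 adjusted over the list alone). The median log2 fold change was 1.85, camera adjusted p = 0.00033, adjusted p = 0.253 with an estimated correlation. HLA-DRA, whose reads can be shared with related genes, fell in OCI-AML2 (−3.70 ± 0.13, adjusted p = 9.37e-16) and rose in MOLM-13 (3.77 ± 0.27, adjusted p = 3.08e-07). Interferon response genes fell in OCI-AML2 (median log2 fold change −1.05, camera adjusted p = 1.65e-05) and MV4-11 (median log2 fold change −0.55, camera adjusted p = 1.32e-05, adjusted p = 0.148 with an estimated correlation). BST2 fell in OCI-AML2 (−1.51 ± 0.07, adjusted p = 3.68e-14) and IFI44L rose there (3.68 ± 0.66, adjusted p = 9.64e-05).

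In MOLM-13 developmental transcription factors of other tissues rose with PCGF1 loss in DMSO. There 12 of 14 measured members rose and 1 fell (12 and 1 adjusted over the list alone), with a median log2 fold change 2.19, camera adjusted p = 1.55e-09, adjusted p = 0.253 with an estimated correlation. The other 27 of the 41 were below the filter, which favours genes a group raises, and without it the median was 1.26. Of the 12 that rose, 7 had a control mean of at least 10. The values of the 41 summed to 2554 and 2274 in control and 6595 and 5811 in the knockout. The sums were 4186 and 4322 against 3639 and 3708 in OCI-AML2, and 4374 and 4790 against 3733 and 4093 in MV4-11. The list was not called in either (median log2 fold change 0.02 and 0.53, camera adjusted p = 0.998 and 0.153). The ovarian factor FOXL2 went from 1.06 ± 0.0163 to 345 ± 13.6 (326-fold, 95% exact interval 90 to 2701). TBX1, a factor of the pharyngeal arches, rose (4.13 ± 0.20, adjusted p = 8.68e-09), as did the homeobox gene IRX3 (1.02 ± 0.09, adjusted p = 3.61e-06), and OLIG2 fell (−0.65 ± 0.13, adjusted p = 0.00325). Of the HOXB, HOXC and HOXD genes too few passed the filter for a set test. Below it were 24, 27 and 26 in OCI-AML2, MV4-11 and MOLM-13. Of those measured 3 of 4, 1 of 1 and 2 of 2 rose (the same adjusted over the list alone), which the filter favours. HOXC8 rose in OCI-AML2 (3.77 ± 0.42, adjusted p = 1.67e-07).

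Between PCGF1 knockout and control cells in DMSO limma called 5464 genes in OCI-AML2 (2834 higher and 2630 lower), 3862 in MV4-11 (1932 and 1930) and 3156 in MOLM-13 (1806 and 1350). In MOLM-13 911 were at least 2-fold higher and 214 at least 2-fold lower. In all 3 lines 421 were higher and 287 lower, against 39.0 and 30.5 for independent lists, and 652 of the 3067 called in at least 2 lines went in opposite directions. Without control DMSO replicate 2 the MV4-11 genes lower were 1223, and without control DMSO replicate 1 those of MOLM-13 741. Without MOLM-13 PCGF1 DMSO replicate 1 that line's count was 1626 (1040 and 586) and the number lower in all 3 lines 172. With DESeq2 the MV4-11 count was 2465.

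Under VTP50469, PCGF1 knockout and control cells differed at more genes. Mitochondrial shares in the knockout were 1.57% and 1.89% in OCI-AML2, and below control at 1.98% and 1.97% in MV4-11 and 1.72% and 1.77% in MOLM-13. MYC was higher in the knockout in OCI-AML2 (1.25 ± 0.05, adjusted p = 1.41e-15), MV4-11 (0.85 ± 0.06, adjusted p = 2.48e-10) and MOLM-13 (0.49 ± 0.07, adjusted p = 0.000107). MEIS1 was higher too, at 315 ± 44.4 against 134 ± 9.87 in MV4-11 (1.22 ± 0.11, adjusted p = 1.21e-08). In MOLM-13 it was at 403 ± 2.21 against 127 ± 2.05 (1.66 ± 0.12, adjusted p = 1.62e-07). In OCI-AML2 MEIS1 had 66 reads against 3 (20.1-fold, 95% exact interval 6.59 to 99.99). HOXA9 was lower in OCI-AML2 (−0.42 ± 0.06, adjusted p = 8.92e-06), higher in MOLM-13 (0.62 ± 0.08, adjusted p = 5.92e-05) and not called in MV4-11 (−0.08 ± 0.07, adjusted p = 0.37). BCOR was not called in MV4-11 (0.07 ± 0.06, adjusted p = 0.368) or MOLM-13 (0.19 ± 0.08, adjusted p = 0.089). In OCI-AML2 it was called lower (−0.17 ± 0.05, adjusted p = 0.00499), a call lost without control VTP50469 replicate 2. Ribosome biogenesis and MYC-associated genes were higher in the knockout. In OCI-AML2 43 of 50 measured members rose (44 adjusted over the list alone), with a median log2 fold change 0.62, camera adjusted p = 1.21e-17. In MV4-11 34 of 50 measured members rose and 2 fell (36 and 2 adjusted over the list alone), with a median log2 fold change 0.32, camera adjusted p = 1.51e-07, adjusted p = 0.119 with an estimated correlation. In MOLM-13 43 of 50 measured members rose (44 adjusted over the list alone), with a median log2 fold change 0.44, camera adjusted p = 7.72e-14.

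Monocyte and macrophage markers were lower in PCGF1 knockout than in control cells under VTP50469. The primary granule and neutrophil lists were not called in OCI-AML2. Of the monocyte and macrophage list in MV4-11, 1 of 31 measured members rose and 30 fell (1 and 30 adjusted over the list alone), with a median log2 fold change −2.42, camera adjusted p = 7.35e-22. In OCI-AML2 3 of 29 measured members rose and 23 fell (3 and 24 adjusted over the list alone), with a median log2 fold change −1.09, camera adjusted p = 3.25e-11. In MOLM-13 3 of 28 measured members rose and 24 fell (3 and 25 adjusted over the list alone), with a median log2 fold change −1.59, camera adjusted p = 1.77e-11, median −1.03 without a filter. LYZ was lower in OCI-AML2 (−3.10 ± 0.06, adjusted p = 9.38e-20) and MOLM-13 (−1.68 ± 0.09, adjusted p = 8.61e-09), and S100A9 in MV4-11 (−5.14 ± 0.08, adjusted p = 3.68e-21). S100A8 went the other way in OCI-AML2 (0.85 ± 0.10, adjusted p = 4.85e-06), as did IRF8 in MOLM-13 (0.69 ± 0.07, adjusted p = 7.63e-06). MHC class II genes were lower in OCI-AML2 (median log2 fold change −3.36, camera adjusted p = 2.72e-06) and MV4-11 (median log2 fold change −1.85, camera adjusted p = 1.51e-07, adjusted p = 0.0636 with an estimated correlation), as were interferon response genes (median log2 fold change −1.06, camera adjusted p = 1.47e-05, and median log2 fold change −1.39, camera adjusted p = 1.07e-10). In MV4-11 integrated stress response genes were higher (median log2 fold change 0.80, camera adjusted p = 1.07e-10, adjusted p = 0.0907 with an estimated correlation), led by DDIT4 (2.27 ± 0.07, adjusted p = 5.34e-16). Cholesterol synthesis genes were lower in MV4-11 (median log2 fold change −0.58, camera adjusted p = 9.88e-10, adjusted p = 0.0907 with an estimated correlation) and higher in MOLM-13 (median log2 fold change 0.79, camera adjusted p = 2.59e-11, adjusted p = 0.148 with an estimated correlation).

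In MOLM-13 under VTP50469 menin-MLL target genes were higher in the knockout (median log2 fold change 0.63, camera adjusted p = 3.97e-09, adjusted p = 0.128 with an estimated correlation), among them the growth factor receptor FLT3 (1.33 ± 0.08, adjusted p = 4.12e-08). Stem and progenitor genes were higher as well (median log2 fold change 0.59, camera adjusted p = 0.000336, adjusted p = 0.128 with an estimated correlation, median 0.36 without a filter). Genes that p53 activates were lower (median log2 fold change −0.45, camera adjusted p = 0.000231, adjusted p = 0.128 with an estimated correlation), with the cell cycle inhibitor CDKN1A down (−0.93 ± 0.09, adjusted p = 3.01e-06) and CCNG1 up (0.54 ± 0.09, adjusted p = 0.00036). Other PRC1 and PRC2 subunits were called higher in this comparison alone of the 21 (median log2 fold change 0.16, camera adjusted p = 0.0413, adjusted p = 0.278 with an estimated correlation, median 0.04 without control VTP50469 replicate 1). That call was lost with DESeq2, with the stricter filter and without control VTP50469 replicate 1 or PCGF1 VTP50469 replicate 1. The immune receptor CD84 was lower in each line, at 74 ± 9.17 against 854 ± 62.3 in OCI-AML2 (−3.52 ± 0.12, adjusted p = 1.56e-16). It was at 77.3 ± 7.18 against 836 ± 90.7 in MV4-11 (−3.42 ± 0.28, adjusted p = 3.74e-07) and 42.7 ± 5.91 against 374 ± 6.13 in MOLM-13 (−3.11 ± 0.19, adjusted p = 4.71e-08).

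In VTP50469 limma called 7800 genes between PCGF1 knockout and control cells in OCI-AML2 (4000 higher and 3800 lower), 6776 in MV4-11 (3418 and 3358) and 5110 in MOLM-13 (2950 and 2160). In all 3 lines 998 were higher and 814 lower, against 171 and 121 for independent lists. Of 5821 called in at least 2 lines, 1160 went in opposite directions. Without MOLM-13 control VTP50469 replicate 1 that line's count was 3376 (1229 lower), and with DESeq2 the MV4-11 count was 3853.

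PCGF1 knockout cells still responded to VTP50469. Their MEIS1 fell in OCI-AML2 from 264 ± 6.1 to 35.9 ± 10.8 (−2.88 ± 0.31, adjusted p = 2.47e-07) and in MV4-11 from 609 ± 8.12 to 315 ± 44.4 (−0.96 ± 0.11, adjusted p = 3e-06). In MOLM-13 MEIS1 was called lower (−0.52 ± 0.12, adjusted p = 0.0171), a call lost without PCGF1 DMSO replicate 1 or PCGF1 VTP50469 replicate 1 or 2. MYC rose in OCI-AML2 (0.32 ± 0.05, adjusted p = 4.05e-05) and was not called in MV4-11 (0.02 ± 0.06, adjusted p = 0.838) or MOLM-13 (−0.14 ± 0.07, adjusted p = 0.283). BCOR rose in MV4-11 (0.31 ± 0.06, adjusted p = 0.0024) and was not called in MOLM-13 (−0.21 ± 0.08, adjusted p = 0.147). In OCI-AML2 BCOR was called higher (0.20 ± 0.05, adjusted p = 0.00464), a call lost without PCGF1 DMSO replicate 2. PCGF1 did not change detectably (−0.20, −0.05 and −0.20 in OCI-AML2, MV4-11 and MOLM-13, adjusted p of 0.252, 0.821 and 0.519). HOXA9 was not called in OCI-AML2 (0.06 ± 0.06, adjusted p = 0.599) or MOLM-13 (−0.03 ± 0.08, adjusted p = 0.891). In MV4-11 it was called higher (0.27 ± 0.07, adjusted p = 0.0109), a call lost without PCGF1 DMSO replicate 2 or PCGF1 VTP50469 replicate 1 or 2. Menin-MLL target genes fell in OCI-AML2 (median log2 fold change −0.27, camera adjusted p = 1.71e-06, adjusted p = 0.115 with an estimated correlation), MV4-11 (median log2 fold change −0.48, camera adjusted p = 1.3e-07, adjusted p = 0.176 with an estimated correlation) and MOLM-13 (median log2 fold change −0.37, camera adjusted p = 1.1e-08, adjusted p = 0.133 with an estimated correlation). MEF2C fell in OCI-AML2 (−2.22 ± 0.06, adjusted p = 1.44e-17) and MV4-11 (−1.98 ± 0.07, adjusted p = 6.83e-15). The monocyte and macrophage list rose in OCI-AML2 (median log2 fold change 1.08, camera adjusted p = 4.39e-12, median 0.58 without a filter), MV4-11 (median log2 fold change 0.60, camera adjusted p = 5.05e-10, adjusted p = 0.0632 with an estimated correlation, median 0.29 with a pseudocount of 5) and MOLM-13 (median log2 fold change 0.39, camera adjusted p = 4.79e-06, adjusted p = 0.133 with an estimated correlation, median 0.22 with a pseudocount of 5 and 0.23 without a filter), and CD4 fell in OCI-AML2 (−1.57 ± 0.08, adjusted p = 2.27e-13). The MV4-11 median was 0.37 with members at 0 in a group set to their bound, 0.35 without PCGF1 DMSO replicate 2 and 0.39 without PCGF1 VTP50469 replicate 1, and the MOLM-13 median 0.25 without PCGF1 DMSO replicate 1. MHC class II genes rose in OCI-AML2 (median log2 fold change 1.82, camera adjusted p = 2.94e-06, adjusted p = 0.0719 with an estimated correlation, median 1.16 with a pseudocount of 5, median 1.18 without PCGF1 DMSO replicate 1) and MV4-11 (median log2 fold change 2.2, camera adjusted p = 1.32e-16, adjusted p = 0.0518 with an estimated correlation) and fell in MOLM-13 (median log2 fold change −1.21, camera adjusted p = 5.19e-06, adjusted p = 0.133 with an estimated correlation).

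In PCGF1 knockout cells 3362 genes were called between treatments in OCI-AML2 (1911 higher and 1451 lower), 2646 in MV4-11 (1264 and 1382) and 1029 in MOLM-13 (650 and 379). In all 3 lines 158 were higher and 56 lower, against 7.41 and 3.38 for independent lists. With DESeq2 the OCI-AML2 genes lower were 937. In MV4-11 the count was 1087 (541 and 546) without PCGF1 VTP50469 replicate 1, 1225 (640 and 585) without replicate 2 and 1321 (753 and 568) without PCGF1 DMSO replicate 2. In MOLM-13 it was 367 (270 and 97) without PCGF1 DMSO replicate 1, 370 (245 and 125) without PCGF1 VTP50469 replicate 1 and 542 (325 and 217) without replicate 2. Across genes, which are not independent replicates, the changes in knockout and control cells had a Pearson correlation of 0.537 in OCI-AML2, 0.458 in MV4-11 and 0.198 in MOLM-13.

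The interaction of guide and treatment tested whether the response differed. A positive value means a higher change with VTP50469 in the knockout. MYC had a positive interaction in OCI-AML2 (1.12 ± 0.07, adjusted p = 8.67e-11), MV4-11 (0.75 ± 0.09, adjusted p = 1.3e-06) and MOLM-13 (0.73 ± 0.10, adjusted p = 0.000337). MEIS1 had one in MV4-11 (0.95 ± 0.16, adjusted p = 0.000125) and MOLM-13 (1.47 ± 0.17, adjusted p = 8.77e-05). In OCI-AML2 its fitted term (3.95 ± 0.44, adjusted p = 5.29e-07) rests on 3 reads in control VTP50469. BCOR had a negative term in OCI-AML2 (−0.72 ± 0.07, adjusted p = 4.75e-08) and MV4-11 (−0.38 ± 0.09, adjusted p = 0.00395) and was not called in MOLM-13 (−0.13 ± 0.12, adjusted p = 0.472). HOXA9 had a positive term in MOLM-13 (0.71 ± 0.12, adjusted p = 0.00125) and none called in MV4-11 (0.06 ± 0.10, adjusted p = 0.707). In OCI-AML2 its term (−0.30 ± 0.09, adjusted p = 0.017) was lost with DESeq2 and without replicate 1 of either control group or replicate 2 of either PCGF1 group. PCGF1 had no called term (0.26, −0.30 and −0.17 in OCI-AML2, MV4-11 and MOLM-13). Ribosome biogenesis and MYC-associated genes had positive interactions in OCI-AML2 (median log2 fold change 0.51, camera adjusted p = 1.35e-22), MV4-11 (median log2 fold change 0.25, camera adjusted p = 1.52e-07, adjusted p = 0.134 with an estimated correlation) and MOLM-13 (median log2 fold change 0.55, camera adjusted p = 1.37e-20). The monocyte and macrophage list had negative ones in OCI-AML2 (median log2 fold change −0.75, camera adjusted p = 1.61e-07), MV4-11 (median log2 fold change −0.91, camera adjusted p = 8.98e-10, adjusted p = 0.0632 with an estimated correlation) and MOLM-13 (median log2 fold change −1.0, camera adjusted p = 7.04e-10, adjusted p = 0.0565 with an estimated correlation). LYZ had a negative term in OCI-AML2 (−2.34 ± 0.08, adjusted p = 1.93e-14) and MOLM-13 (−2.24 ± 0.12, adjusted p = 6.4e-07), and CSF1R went against the list in OCI-AML2 (1.36 ± 0.16, adjusted p = 7.9e-07). Cholesterol synthesis genes had negative interactions in OCI-AML2 (median log2 fold change −0.38, camera adjusted p = 4.9e-08, adjusted p = 0.243 with an estimated correlation) and MV4-11 (median log2 fold change −0.57, camera adjusted p = 8.41e-11, adjusted p = 0.0745 with an estimated correlation) and a positive one in MOLM-13 (median log2 fold change 1.03, camera adjusted p = 1.75e-17, adjusted p = 0.13 with an estimated correlation).

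Interaction was called for 3645 genes in OCI-AML2 (1987 positive and 1658 negative), 3842 in MV4-11 (2003 and 1839) and 2731 in MOLM-13 (1621 and 1110). In all 3 lines 273 were positive and 139 negative, against 30.8 and 16.0 for independent lists. The MOLM-13 count was 1369 (905 and 464) without control VTP50469 replicate 1, 1781 (677 negative) without PCGF1 VTP50469 replicate 1 and 1815 (672 negative) without PCGF1 DMSO replicate 1. Without the first of these 79 were negative in all 3 lines, and with DESeq2 the MV4-11 count was 2095.

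Genes chosen by their response in a line favour a return towards control in that line. For each line a set was therefore taken from genes called lower, or higher, with VTP50469 in control cells of both other lines. In OCI-AML2 under VTP50469 the 1329 genes lowered in the other lines had a median log2 fold change of 0.38 in PCGF1 knockout against control cells (68.5% called higher and 7.52% lower, camera adjusted p = 8.64e-25). The median was 0.28 over 1430 genes in MV4-11 (camera adjusted p = 3.29e-21) and 0.27 over 1718 genes in MOLM-13 (camera adjusted p = 7.85e-15). Genes raised in the other lines had medians of −0.43 over 1096 genes in OCI-AML2 (camera adjusted p = 3.07e-20) and −0.44 over 1257 in MV4-11 (camera adjusted p = 2.79e-27). In MOLM-13 the median was −0.22 over 1664 genes (camera adjusted p = 2.87e-11). With an estimated correlation the largest adjusted p of these 6 tests was 0.0185. Under DMSO the medians were 0.08, 0.04 and −0.01 for the lowered sets and −0.12, −0.16 and −0.09 for the raised sets in OCI-AML2, MV4-11 and MOLM-13. The lowered set of MOLM-13 was not called there (adjusted p = 0.5). Calls were lost for the lowered set of MV4-11 (adjusted p = 0.122 with an estimated correlation) and the raised set of MOLM-13 (adjusted p = 0.167 with an estimated correlation).

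**Figure D4:**
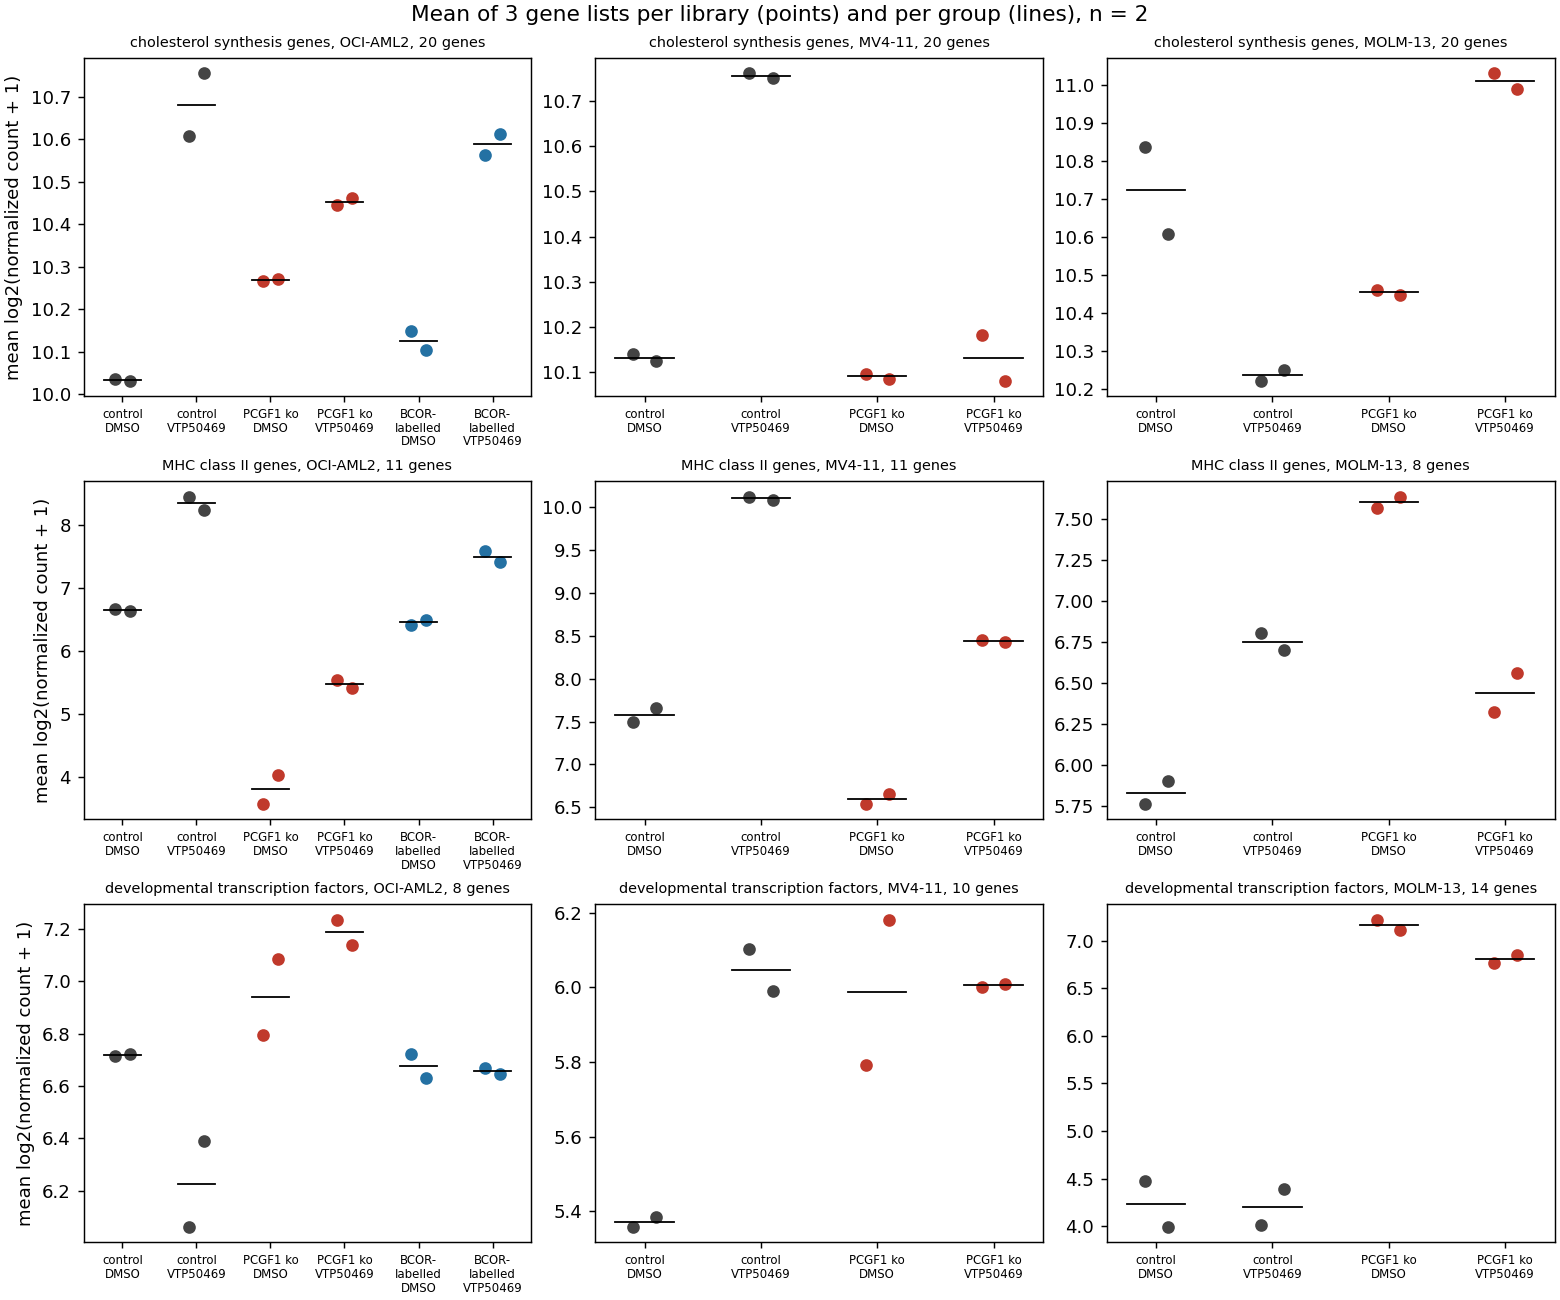
Mean log2 value of the cholesterol synthesis, MHC class II and developmental transcription factor lists in each library (points) by group in each line, with lines at the group means. The cholesterol list falls with VTP50469 in MOLM-13 control cells (median log2 fold change −0.49) and rises in OCI-AML2 (0.68) and MV4-11 (0.66).

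The OCI-AML2 libraries labelled BCOR knockout were compared with the same controls. Under DMSO MYC was at 17069.5 ± 474 against 17072 ± 522 (adjusted p = 1) and MEIS1 at 310.1 ± 10 against 307 ± 6.41 (adjusted p = 0.986). Neither HOXA9 (0.09 ± 0.06, adjusted p = 0.47) nor PCGF1 (−0.08 ± 0.12, adjusted p = 0.772) was called. Of the monocyte and macrophage markers 2 of 29 measured members rose and 10 fell (2 and 13 adjusted over the list alone), with a median log2 fold change −0.39, camera adjusted p = 2.77e-07, adjusted p = 0.0904 with an estimated correlation. CD4 fell (−1.0 ± 0.08, adjusted p = 1.23e-08), as did CSF1R (−0.84 ± 0.11, adjusted p = 2.6e-05), and CD68 rose (0.30 ± 0.06, adjusted p = 0.000989). PRC1.1 subunits were called higher here alone of the 21 comparisons (median log2 fold change 0.07, camera adjusted p = 0.0199, adjusted p = 0.545 with an estimated correlation). BCOR is itself a member, and the list without it, tried after seeing this, was not called (median 0.05, camera adjusted p = 0.282). With BCOR the median was 0.01 without BCOR DMSO replicate 1 and 0.03 without control DMSO replicate 2. That call was lost without BCOR DMSO replicate 1. These were the deepest and the shallowest groups of the line.

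Under VTP50469 the libraries labelled BCOR knockout had more MYC than control cells (0.56 ± 0.05, adjusted p = 1.45e-08), MEIS1 values of 1.01 and 2.5, and HOXA9 not called (−0.07 ± 0.06, adjusted p = 0.451). PCGF1 was called higher (0.39 ± 0.12, adjusted p = 0.016), a call lost with DESeq2 and without control VTP50469 replicate 1 or BCOR VTP50469 replicate 2. Of the ribosome biogenesis and MYC-associated genes 36 of 50 measured members rose (37 and 1 adjusted over the list alone), with a median log2 fold change 0.31, camera adjusted p = 6.42e-16. Of the monocyte and macrophage markers 21 of 29 measured members fell (24 and 1 adjusted over the list alone), with a median log2 fold change −0.60, camera adjusted p = 4.73e-13. LYZ was lower (−1.16 ± 0.06, adjusted p = 5.02e-12). The receptor kinase FGFR1 was at 1459 ± 108 against 179.7 ± 9.41 (3.01 ± 0.07, adjusted p = 8.93e-19), and GATA2 was higher (2.42 ± 0.08, adjusted p = 1.39e-16). The 1329 genes lowered in the other lines had a median of 0.13 (camera adjusted p = 7.35e-13) and the 1096 raised −0.18 (camera adjusted p = 6.28e-12).

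Within the libraries labelled BCOR knockout VTP50469 lowered MYC (−0.25 ± 0.05, adjusted p = 0.000363), brought MEIS1 from 310.1 ± 10 to 1.01 and 2.5 (adjusted p = 4.75e-14) and lowered menin-MLL target genes (median log2 fold change −0.41, camera adjusted p = 6.31e-06, adjusted p = 0.121 with an estimated correlation). It raised the monocyte and macrophage list (median log2 fold change 1.34, camera adjusted p = 4.57e-14), with LYZ up (4.15 ± 0.06, adjusted p = 4.39e-22). HOXA9 was called higher (0.19 ± 0.06, adjusted p = 0.0226), a call lost with edgeR, with DESeq2, without a filter and without BCOR DMSO replicate 1 or 2 or BCOR VTP50469 replicate 1. PCGF1 (0.01 ± 0.12, adjusted p = 0.939) and BCOR (0.09 ± 0.05, adjusted p = 0.167) did not change detectably. The interaction was positive for MYC (0.56 ± 0.07, adjusted p = 1.12e-05) and negative for BCOR (−0.83 ± 0.07, adjusted p = 3.28e-08). It was not called for MEIS1 (adjusted p = 0.968), HOXA9 (−0.17 ± 0.09, adjusted p = 0.248) or PCGF1 (0.47 ± 0.17, adjusted p = 0.0595). Ribosome biogenesis and MYC-associated genes had a positive interaction (median log2 fold change 0.30, camera adjusted p = 8.19e-13) and the monocyte and macrophage list a negative one (median log2 fold change −0.29, camera adjusted p = 0.00258, adjusted p = 0.219 with an estimated correlation, median −0.16 with edgeR and −0.17 with DESeq2, median −0.12 without BCOR DMSO replicate 1). Across genes the responses of these libraries and of control cells had a Pearson correlation of 0.706.

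Limma called 1029 genes between the libraries labelled BCOR knockout and control in DMSO (416 higher and 613 lower) and 3789 in VTP50469 (2045 and 1744). It called 5701 between treatments (2990 and 2711) and 2031 for the interaction (1149 and 882). In VTP50469 the genes higher were 1351 without BCOR VTP50469 replicate 2 and the genes lower 1130 without control VTP50469 replicate 2, where the interaction had 521 negative. The DMSO count was 430 (169 and 261) and 442 (187 and 255) without control DMSO replicate 1 or 2 and 591 (208 and 383) and 585 (205 and 380) without BCOR DMSO replicate 1 or 2. The interaction count was 1259 (752 and 507) and 1110 (651 and 459) without control DMSO replicate 1 or 2 and 1331 (556 negative) without BCOR DMSO replicate 2. With DESeq2, which used 1 library of the BCOR VTP50469 group, the counts were 625 in DMSO, 1813 in VTP50469, 3263 between treatments and 966 for the interaction.

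Against PCGF1 knockout cells, the libraries labelled BCOR knockout had more PCGF1 in DMSO (0.85 ± 0.12, adjusted p = 3.92e-06) and VTP50469 (1.06 ± 0.12, adjusted p = 1.25e-07). BCOR was higher in DMSO (0.29 ± 0.05, adjusted p = 4.94e-05) and, except with DESeq2, in VTP50469 (0.18 ± 0.05, adjusted p = 0.00432). MYC was not called in DMSO (−0.12 ± 0.05, adjusted p = 0.0577) and was lower in VTP50469 (−0.69 ± 0.05, adjusted p = 1.26e-10). MEIS1 was not called in DMSO (adjusted p = 0.613) and was lower in VTP50469 (adjusted p = 1.56e-09). HOXA9 was higher in VTP50469 (0.34 ± 0.06, adjusted p = 0.000166). In DMSO it was called higher (0.21 ± 0.06, adjusted p = 0.0144), a call lost with DESeq2 and without PCGF1 DMSO replicate 1 or BCOR DMSO replicate 1 or 2. MHC class II genes were higher in DMSO (median log2 fold change 3.20, camera adjusted p = 6.36e-09, median 1.64 with a pseudocount of 5) and VTP50469 (median log2 fold change 2.34, camera adjusted p = 6.93e-07). CSF1R was higher in DMSO (3.15 ± 0.11, adjusted p = 1.33e-15) and ELANE lower (−3.16 ± 0.06, adjusted p = 1.02e-21). These comparisons called 5184 genes in DMSO (2426 higher and 2758 lower) and 5919 in VTP50469 (2881 and 3038), the latter 3251 with DESeq2.

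Both OCI-AML2 guides were set against the same controls. In DMSO 297 genes were called higher and 335 lower in both, 632 in all, against 80.4 and 109.9 for independent lists, and 141 went in opposite directions. Groups simulated 20 times without any change gave a mean of 0.1 shared calls. The covariance of the log2 fold changes was 0.0935, against 0.0312 in the simulations, while the correlation, 0.310, was below the simulated 0.404. In VTP50469 1707 genes were higher and 1253 lower in both, 2960 in all, against 558 and 452 for independent lists and 0.15 in the simulations. There 202 went in opposite directions, the covariance was 0.264 against 0.0441, and the correlation 0.544 against 0.524. The 2 controls per treatment were not split between the guides, so part of the excess may come from them. Simulated calls, with no gene changed, cannot measure that part. In DMSO the shared calls numbered 287 and 294 without control DMSO replicate 1 or 2 and 361 and 355 without BCOR DMSO replicate 1 or 2. With DESeq2 they were 421 in DMSO and 1520 in VTP50469.

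Of the lists tested, the MYC network, the BCL2 family and the erythroid and megakaryocyte markers were not called by camera in any of the 21 comparisons. In control cells given VTP50469 their medians in OCI-AML2, MV4-11 and MOLM-13 were 0.04, 0.06 and −0.03, 0.12, −0.01 and 0.22 and −0.81, −0.26 and −0.46. The last is −0.02 with members at 0 in a group set to their bound. Of the B cell markers 4, 2 and 4 were measured in these lines, and of the T and NK cell markers 2, 1 and 4, too few for a set test. With VTP50469 0 B cell markers rose and 2 fell in OCI-AML2 (0 and 3 adjusted over the list alone). In MV4-11 1 rose and 1 fell (1 and 1 adjusted over the list alone), and in MOLM-13 0 rose and 1 fell (0 and 1 adjusted over the list alone). Of the T and NK cell markers 2 fell in OCI-AML2 (2 adjusted over the list alone), 1 rose in MV4-11 (1 adjusted over the list alone) and 2 rose in MOLM-13 (3 rose and 1 fell adjusted over the list alone).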

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

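The results below had a called interaction of guide and treatment or opposite calls in different lines. All tests used to weigh them were chosen after results had been seen, as was the restriction of the differences between lines to effects called in each line.

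Lists and sets of genes are given in this paragraph only where the call held with an estimated correlation too (2 of 6 lists called in OCI-AML2, 0 of 9 in MV4-11 and 1 of 10 in MOLM-13 for PCGF1 knockout, 1 of 4 for the libraries labelled BCOR knockout). In OCI-AML2 the interaction of PCGF1 knockout and VTP50469 was called for BCOR (−0.72), MYC (1.12), MEIS1 (3.95, fitted, with 3 reads in control VTP50469), HOXA9 (−0.30), ribosome biogenesis and MYC-associated genes (median 0.51) and monocyte and macrophage markers (−0.75). The sets lowered and raised by the inhibitor in the other lines had medians of 0.28 and −0.32. The HOXA9 call was lost with thinned reads, with DESeq2 and without replicate 1 of either control group or replicate 2 of either PCGF1 group. For the libraries labelled BCOR knockout the interaction was called for BCOR (−0.83), MYC (0.56), ribosome biogenesis and MYC-associated genes (0.30) and the lowered (0.14) and raised sets (−0.14). In MV4-11 it was called for BCOR (−0.38), MYC (0.75), MEIS1 (0.95) and the lowered (0.25) and raised sets (−0.28). In MOLM-13 it was called for MYC (0.73), MEIS1 (1.47), HOXA9 (0.71), ribosome biogenesis and MYC-associated genes (0.55) and the lowered (0.26) and raised sets (−0.16).

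Other results were called in opposite directions in different lines with each library on its side. Differences between lines were not tested. Of the gene lists in this paragraph, MHC class II genes with PCGF1 loss in OCI-AML2 under DMSO kept the call with an estimated correlation (adjusted p = 0.0337), and each of the others lost it (0.0518 to 0.817). Cholesterol synthesis genes in control cells given VTP50469 had medians of 0.68 in OCI-AML2, 0.66 in MV4-11 and −0.49 in MOLM-13, and HOXA9 changed by 0.36, 0.21 and −0.74. The MV4-11 call of HOXA9 was lost without control DMSO replicate 1 or 2 or control VTP50469 replicate 2. With PCGF1 loss in DMSO the medians were 0.14 in OCI-AML2 and −0.11 in MOLM-13 for ribosome biogenesis and MYC-associated genes, and 0.18 and −0.24 for cholesterol synthesis genes (−0.13 without MOLM-13 control DMSO replicate 1). They were 0.26, 0.54 and −0.71 in OCI-AML2, MV4-11 and MOLM-13 for primary granule genes, and −2.87, −1.22 and 1.85 for MHC class II genes. The granule call was lost in OCI-AML2 without BCOR DMSO replicate 1 or 2. In MOLM-13 it was lost with the stricter filter and without control DMSO replicate 1 or PCGF1 DMSO replicate 2. With PCGF1 loss in VTP50469 cholesterol synthesis genes had medians of −0.24, −0.58 and 0.79 in the same order, and HOXA9 changed by −0.42 in OCI-AML2 and 0.62 in MOLM-13. The OCI-AML2 cholesterol call was lost with DESeq2 and without control VTP50469 replicate 2 (median −0.15). With VTP50469 in PCGF1 knockout cells MHC class II genes had medians of 1.82, 2.2 and −1.21, the first 1.18 without PCGF1 DMSO replicate 1.

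BCOR was higher in the OCI-AML2 libraries labelled BCOR knockout than in control under DMSO (0.84). Thinned reads gave 0.82 (SE 0.055), but at 3183 to 4495 reads this decides little about depth. The median of all genes was −0.0025, so the distance of BCOR from it, 0.84 (SE 0.0486), restates the change and decides little about scaling. A candidate biological explanation is that loss of PRC1.1 raises BCOR transcription in cells without the inhibitor. BCOR was called higher in PCGF1 knockout cells under DMSO in all 3 lines. The smallest change, 0.32 in MOLM-13, lost its call without control DMSO replicate 1 or PCGF1 DMSO replicate 1. Under VTP50469 these changes were −0.17, 0.07 and 0.19, and a wrong label of the libraries was not tested.

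The fall of cholesterol synthesis genes with VTP50469 in MOLM-13 control cells, against a rise in the other lines, was weighed against depth and scaling. The MOLM-13 control libraries held 19067297 to 20280727 reads, so thinning (median −0.47, adjusted p = 5.98e-07) decides little about depth. The distance from the median of all genes (0.0099) was −0.5, which likewise decides little about scaling. Over all alternatives run for it the median ranged from −0.62 to −0.36 (weakest without control DMSO replicate 1) and the adjusted p from 7.55e-10 to 1.4e-05, all at the preset correlation, while with an estimated correlation the call was lost (adjusted p = 0.248). No biological explanation was tested.

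Developmental transcription factors of other tissues had a median of 2.19 with PCGF1 loss in MOLM-13 under DMSO. The knockout libraries held 24194971 and 17440817 reads, on either side of the control libraries (20280727 and 19910703). Thinning (median 2.26, adjusted p = 3.74e-09) thus decides little about depth. Over all alternatives run the median of the list ranged from 1.26 (no filter) to 2.49. The adjusted p ranged from 1.54e-13 to 1.66e-07 at the preset correlation, but with an estimated one the call was lost (adjusted p = 0.253). The 4232 other genes in the weaker part of the list's range had a median of 0.213 (quartiles −0.238 and 0.827). Of 10000 random lists matched on mean value the highest median was 1.04. Control level (8 factors at 10 or more, 14 in knockout) and correlation between members were not matched. Reads from epithelial, mesenchymal or neural cells would bring abundant transcripts. EPCAM and CDH1, COL1A2 and SPARC, and STMN2 were at 0, although KRT18, COL1A1 and TUBB3 were called higher (0.97, 1.83 and 1.18). The highest marker median of any of these kinds in a knockout library was 3.47. The 12 factors that rose (179.8 and 185) were picked for that, so the gap decides little. Other kinds of cells and biological explanations were not tested.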

How the results depend on the processing

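All alternatives but the thinning of reads and PRC1.1 subunits without BCOR were chosen before results were seen. Of 1362 tested results, most picked for being called, 1321 were called. Of these, 1117 held under every alternative run for them and 204 did not. None of the 1321 reversed in direction. Such results do not speak for all genes. Leaving out 1 library ended 513 calls, counted once per library and result, DESeq2 ended 100, thinning 32, no filter 28, edgeR 27, the stricter filter 13, a pseudocount of 5 ended 9 and TMM rescaling 1. No rescaling moved the median of all genes by over 0.08. Where a library is left out, its partner is taken to vary like the other groups. The same holds for groups with 1 library in edgeR and DESeq2, so these change tool and libraries together. Uncalled lists were refitted only for the counts of lists called.

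DESeq2 called fewer genes than limma in each comparison but the inhibitor in PCGF1 knockout cells of MOLM-13 (1200 against 1029). In OCI-AML2 it called 3263 for the inhibitor in the libraries labelled BCOR knockout (5701 by limma), 625 against control in DMSO (1029), 1813 in VTP50469 (3789), 966 for the interaction (2031) and 3251 against PCGF1 knockout in VTP50469 (5919). In MV4-11 it called 4139 for the inhibitor in control cells (7241), 1746 in PCGF1 knockout cells (2646), 2465 for PCGF1 loss in DMSO (3862), 3853 in VTP50469 (6776) and 2095 for the interaction (3842). The genes shared by both guides of OCI-AML2 numbered 421 in DMSO (632) and 1520 in VTP50469 (2960). The gene lists called for the interaction in the libraries labelled BCOR knockout were 7 with DESeq2 and 7 with edgeR (4 by limma). With edgeR 85 genes were lower in all 3 lines for the inhibitor in PCGF1 knockout cells (56). Without a filter 5 gene lists were called in OCI-AML2 for the libraries labelled BCOR knockout against control in DMSO (3) and 7 for them against PCGF1 knockout in VTP50469 (4). Of the calls by these tools 78.2% to 99.5% were also calls by limma. Beyond the fewer libraries, the cause was not tested.

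Leaving out 1 library gave these ranges. In OCI-AML2 the libraries labelled BCOR knockout against control in DMSO had 430 to 1095 genes (lowest without control DMSO replicate 1, 442 without replicate 2, 591 and 585 without BCOR DMSO replicate 1 or 2), with 1 to 3 gene lists called (1 without BCOR DMSO replicate 1). Their interaction had 1110 to 2151 (lowest without control DMSO replicate 2, 1259 without replicate 1, 1331 without BCOR DMSO replicate 2), and the genes shared by both guides in DMSO numbered 287 to 666 (lowest without control DMSO replicate 1). The inhibitor in PCGF1 knockout cells gave 1087 to 2878 in MV4-11 (lowest without PCGF1 VTP50469 replicate 1) and 367 to 1279 in MOLM-13 (lowest without PCGF1 DMSO replicate 1, 370 without PCGF1 VTP50469 replicate 1), where 6 to 11 lists were called (6 without PCGF1 DMSO replicate 2). In MOLM-13 control VTP50469 replicate 1 gave the lowest counts for the inhibitor in control cells (3252 to 5308), PCGF1 loss in VTP50469 (3376 to 5275) and the interaction (1369 to 2843). PCGF1 loss in DMSO gave 1626 to 3066 (lowest without PCGF1 DMSO replicate 1). In all 3 lines 79 to 139 genes were negative in the interaction (79 without MOLM-13 control VTP50469 replicate 1) and 172 to 292 lower with PCGF1 loss in DMSO (172 without MOLM-13 PCGF1 DMSO replicate 1). For the inhibitor in PCGF1 knockout cells 98 to 171 were higher (98 without MOLM-13 PCGF1 VTP50469 replicate 1, 103 without PCGF1 DMSO replicate 1) and 24 to 61 lower (24 without the former, 25 without the latter, 34 without PCGF1 VTP50469 replicate 2).

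The values that changed sign belong to genes not called in limma. In OCI-AML2 MYC in the libraries labelled BCOR knockout against control in DMSO was −0.0313 to 0.0311 with a library left out, 0.000928 with TMM and 0.000403 with edgeR. MEIS1 was −0.0161 to 0.0496 in DMSO (−0.00546 thinned) and −0.472 to 0.420 in VTP50469 (0.537 with edgeR, 0.552 with DESeq2). Its interaction was −0.489 to 0.403 (0.520 and 0.536). BCOR in VTP50469 was −0.0143 to 0.0389 (−0.0135 with DESeq2). PCGF1 was −0.190 to 0.0260 in DMSO and −0.0941 to 0.122 for the inhibitor. For the inhibitor in PCGF1 knockout cells of MV4-11 MYC was −0.0140 to 0.0615 and PCGF1 −0.182 to 0.0887. In MOLM-13 PCGF1 was −0.0833 to 0.0132 for the inhibitor in control cells, −0.455 to 0.0502 in PCGF1 knockout cells and −0.420 to 0.0852 for the interaction.

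Replicate numbers do not pair the libraries. Deviations of libraries with the same number had correlations of −0.0736 to 0.0552 in OCI-AML2, −0.0916 to 0.0354 in MV4-11 and −0.0756 to 0.0376 in MOLM-13. A block for the replicate number moved no count by over 1.5 times and ended 8 calls, among them MYC with PCGF1 loss in MOLM-13 under DMSO (adjusted p = 0.0536 with the block, 0.0274 without, 0.00445 to 0.0849 over its alternatives).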

Other observations

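The genes in this part were named by the rule given above, and no test in it was added after seeing results. PRG2, PRG3 and CLC, which eosinophils express, were 3 of the 5 largest rises in the libraries labelled BCOR knockout against control under DMSO, beside DEFA3 and DEFA1B. No list of eosinophil genes was tested. PRG2 and PRG3 went from 3659.6 ± 54.4 to 23778 ± 2032 (2.70 ± 0.13, adjusted p = 2.29e-05) and from 278 ± 19 to 1866 ± 79.5 (2.75 ± 0.14, adjusted p = 6.51e-07). CLC, which forms Charcot-Leyden crystals, went from 57.2 ± 3.03 to 365 ± 50.3 (2.65 ± 0.14, adjusted p = 2.29e-11). The primary granule and granulocyte progenitor genes as a list were not called in the same comparison (median log2 fold change −0.11, camera adjusted p = 0.891).

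In MV4-11 PRG2 was among the largest rises with PCGF1 loss in DMSO, from 109 ± 54.8 to 1569 ± 34 (3.94 ± 0.47, adjusted p = 0.00562), and among the largest falls with VTP50469 in PCGF1 knockout cells (−3.51 ± 0.47, adjusted p = 0.0126). The call of the fall was lost without PCGF1 DMSO replicate 2 or PCGF1 VTP50469 replicate 1 or 2.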
